A study of Mus musculus with 8 samples.

How the data were processed

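RNA from 8 fasted mouse livers, 4 control and 4 hydrogen water, was extracted with an RNeasy Mini kit, amplified with the Ambion WT Expression kit and labelled with biotin, per the labels' protocols. Groups were taken from the sample titles and descriptions. The treatment text in the labels is identical for all 8 samples, controls included, and was not used to assign groups. Mice were housed at 24 degrees C with 12 h of light and 12 h of dark, per the labels.

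The authors deposited 1 table of log2 signals, with 1 value per probe set and array, made with Affymetrix Expression Console per the submitters' processing notes. The version and the background, normalization and summary method are not given in the sources used here, nor is a genome build. That the scale is log2 was read from the values. No depth applies to arrays; precision is given by the spread over 4 arrays per group.

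The table held 35556 probe sets: 21789 with 1 gene symbol, 1621 with several and 12146 unnamed here. Symbols came from the platform annotation and were updated through Entrez identifiers in a RefSeq table of the assembly GRCm38.p6, which was used for names only; 19856 of the 19938 genes matched. Each gene was represented by its probe set with the highest mean signal; of 999 genes with more than 1 probe set, 370 had probe sets that differed in direction. No filter on level was applied. Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on log2 signals, 2 groups, no covariate, two-sided), with Benjamini-Hochberg adjustment over 19938 genes and a threshold of 0.05. Residual degrees of freedom were 6 and prior degrees of freedom 5.88.

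The 46 lists (32 gene lists and 14 marker lists) and the rule for named genes were fixed before the data were examined. Of 934 distinct genes on the lists, some of them on several, 838 had a probe set naming that gene alone. The rest are not analysed here. Matching of older symbols to the lists was corrected after a first pass had shown list results, because some synonyms had been matched to other genes; 10 lists passed before and after. Lists were tested with limma's camera (correlation preset at 0.01, two-sided), adjusted over the 46 lists. The per-array mean of each list, over log2 signals centred per gene, was tested with a two-sided exact permutation test over all 70 assignments of the arrays.

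Named genes were, first, those past the threshold, of which there were 0; then, in each direction, the 10 genes with the smallest unadjusted p among genes above the median level (5.87), leaving out provisional gene models; then the 4 members with the smallest unadjusted p in the direction of each list that passed camera; and 19 genes named whatever their values. In all 75 genes were named.

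The alternatives tried were a filter on dim probe sets, every probe set or the mean of a gene's probe sets, probe sets with several symbols, quantile normalization, median centring, a trended and robust variance model, array weights, the replicate number as a block, each array left out in turn, camera with an estimated correlation, fry, the permutation test, dim list members left out and medians over members. Leaving out both control 3 and hydrogen water 4, and leaving out small non-coding RNAs, were chosen after seeing the data. A pseudocount was not needed because the values were already on a log2 scale.

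The gene test was tested on simulated data for hydrogen water against control, with 19938 genes, 4 arrays per group and 200 changed genes per run. It recovered 35.2% of genes changed by 0.5 on the log2 scale, 87.6% at 1, 99.0% at 1.5 and 99.6% at 2, with 5.58% of calls false. These sizes were mixed within each run. The shares hold for 200 changed genes per run: the adjusted threshold is stricter where fewer genes change, so recovery would then be lower. In simulations without change it made 0 calls. Noise was simulated independently between genes, so these runs do not cover correlation between the genes of a list. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.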

Results

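Hepatic gene expression was measured in 8 liver samples of C57BL6 mice, each hybridised to its own Affymetrix Mouse Gene 1.0 ST array, a 1-colour platform that reads most transcripts through several probes along their length. Livers were taken after 17 h of fasting. In the hydrogen water group (4 arrays), mice had drunk water containing dissolved molecular hydrogen for 4 weeks from 7 weeks of age; the other 4 arrays came from control mice. The median log2 signal of an array over all probe sets lay between 5.27 and 5.37. The correlation between arrays over the 19938 genes tested lay between 0.988 and 0.995. Control 3 had the lowest mean correlation with its own group (0.989). Hydrogen water 4 carried the lowest signal of small nucleolar RNAs, with a per-array median of −0.88 on the log2 scale around each gene's mean, against −0.26 on control 3 and 0.30 on hydrogen water 1. The number of arrays limits the precision of every comparison given here. The labels describe the samples as mice but do not state outright that each array is a separate animal; if they are not, p-values measure only the spread between these samples.

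The comparison asked which transcripts differed between the fasted livers of the hydrogen water and control groups. The lowest unadjusted p belonged to Ppp1r3c, a regulatory subunit that directs protein phosphatase 1 to glycogen (transcript cluster 10467206). Its log2 signal was 7.38 ± 0.25 (SD, n = 4) with hydrogen water and 8.48 ± 0.42 (SD, n = 4) in controls, a difference of −1.11 (SE 0.19). Pnisr, a serine- and arginine-rich nuclear protein gene (transcript cluster 10503570), stood at 7.40 ± 0.41 (SD, n = 4) against 6.43 ± 0.06 (SD, n = 4), a difference of 0.97 (SE 0.17). Neither gene passed the test over all genes: limma with Benjamini-Hochberg adjustment gave an adjusted p of 0.558 for both.

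No gene passed that threshold. Of 19938 genes tested with limma, 0 had an adjusted p under 0.05 and the lowest adjusted p was 0.558. At an unadjusted p under 0.05 there were 1429 genes, 718 higher and 711 lower with hydrogen water, where 996.9 would be found by chance on average. Other groupings of the arrays could give more: controls 1, 2 and 4 with hydrogen water 2 against the rest gave 2122. At an unadjusted p under 0.01 there were 308 genes, 162 higher and 146 lower, against 199.38 by chance on average. That split depended on scaling: quantile normalization gave 135 higher and 233 lower, and centring each array on its median gave 89 higher and 237 lower. The 4 values of a group lay wholly apart from those of the other in 750 genes, or 3.76%, where chance gives 2.86% on average. That share was not computed for other groupings of the arrays. The median difference over all genes was −0.00 with a median SE of 0.12, and 13 genes differed by at least 1 on the log2 scale.

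Among genes above the median level, leaving out provisional gene models, those with the smallest unadjusted p in each direction are given as values, since none passed the adjusted threshold. On the higher side, the differences were 1.48 (SE 0.34) for Fut11, a member of the fucosyltransferase family, 1.01 (SE 0.22) for Leng8 and 0.89 (SE 0.18) for Wsb1, a SOCS box protein gene. The small nucleolar RNA Snord14e stood at 8.08 ± 0.43 (SD, n = 4) with hydrogen water and 6.67 ± 0.57 (SD, n = 4) in controls. Rsrp1, a gene for an arginine- and serine-rich protein, differed by 0.78 (SE 0.18). Slc25a22, a mitochondrial glutamate carrier, differed by 0.70 (SE 0.16), the tubulin gene Tuba8 by 0.65 (SE 0.13), the Hippo pathway transcription factor Tead1 by 0.54 (SE 0.12) and Arhgef7 by 0.48 (SE 0.11). On the lower side, the sulfotransferase Sult1b1 differed by −0.81 (SE 0.17), the choline transporter-like gene Slc44a3 by −0.68 (SE 0.14), Car8 by −0.66 (SE 0.15) and the glucuronosyltransferase Ugt2b35 by −0.63 (SE 0.14). Zfp593, Lipt2 and Hddc2 differed by −0.61 (SE 0.13), −0.59 (SE 0.13) and −0.59 (SE 0.11). The tight junction gene Ocln differed by −0.55 (SE 0.11) and the Mediator subunit Med28 by −0.49 (SE 0.11). The adjusted p of these 18 genes, from limma, lay between 0.558 and 0.617.

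**Figure D1:**
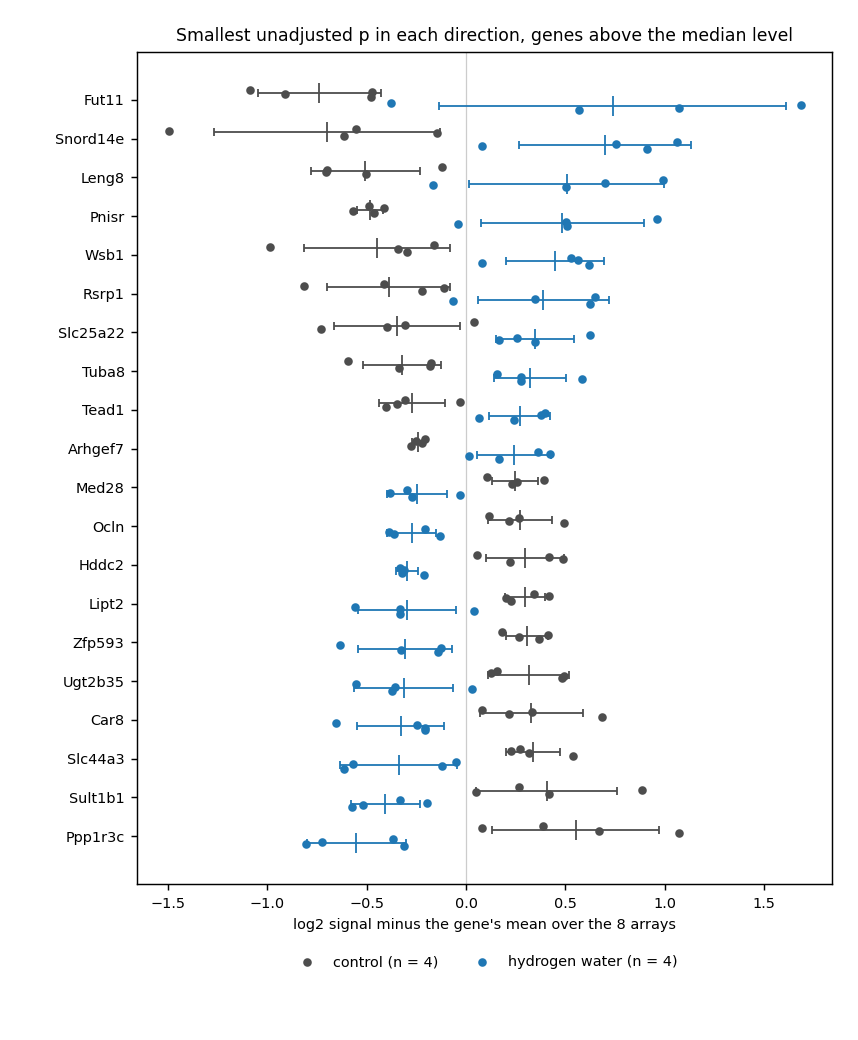
Log2 signal of the 20 genes with the smallest unadjusted p among genes above the median level other than provisional models, 10 in each direction, minus each gene's mean over the 8 arrays (horizontal axis, log2); points are arrays, vertical ticks group means and bars the SD over 4 arrays. Ppp1r3c differs by −1.11 and Fut11 by 1.48, and no gene passed the adjusted threshold.

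Of the genes fixed in advance for fasting metabolism and stress, 0 passed the adjusted threshold. Pck1, the rate-limiting enzyme of gluconeogenesis, stood at 13.50 ± 0.19 (SD, n = 4) with hydrogen water and 13.49 ± 0.11 (SD, n = 4) in controls, a difference of 0.01 (95% interval −0.24 to 0.27). Fgf21, a hormone that the liver secretes in fasting, stood at 7.22 ± 0.31 (SD, n = 4) and 7.21 ± 0.42 (SD, n = 4), a difference of 0.01 (95% interval −0.44 to 0.46). Cpt1a, which commits fatty acids to mitochondrial oxidation, differed by 0.15 (95% interval −0.09 to 0.38). Intervals were wide for Pdk4 (−0.15, 95% interval −1.20 to 0.91), for the transcriptional coactivator Ppargc1a (0.09, 95% interval −0.67 to 0.85) and for Cyp7a1, the rate-limiting enzyme of bile acid synthesis (0.12, 95% interval −0.97 to 1.21). Of the 2 probe sets of Ppargc1a, only 1 was higher with hydrogen water. The lipogenic genes Fasn and Scd1 differed by −0.08 (SE 0.26) and −0.11 (SE 0.11). The oxidant defence genes Hmox1 and Sod2 differed by −0.03 (SE 0.15) and −0.04 (SE 0.11), whereas Nqo1, an NRF2 target, differed by −0.49 (95% interval −0.95 to −0.03, limma adjusted p = 0.687). Much of the Nqo1 difference came from control 1, at 8.31 against 7.16 to 7.66 on the other controls and 6.99 to 7.21 with hydrogen water. The proliferation marker Mki67, at a low level of 4.62 against 4.40, differed by 0.22 (SE 0.09; limma adjusted p = 0.687). Hspa8, Per1, Col1a1 and Saa1 differed by 0.12 (SE 0.12), 0.26 (SE 0.17), 0.05 (SE 0.10) and −0.20 (SE 0.23). Of the 19 genes fixed in this way 16 had a probe set naming a single gene; the rest are not analysed here.

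**Figure D2:**
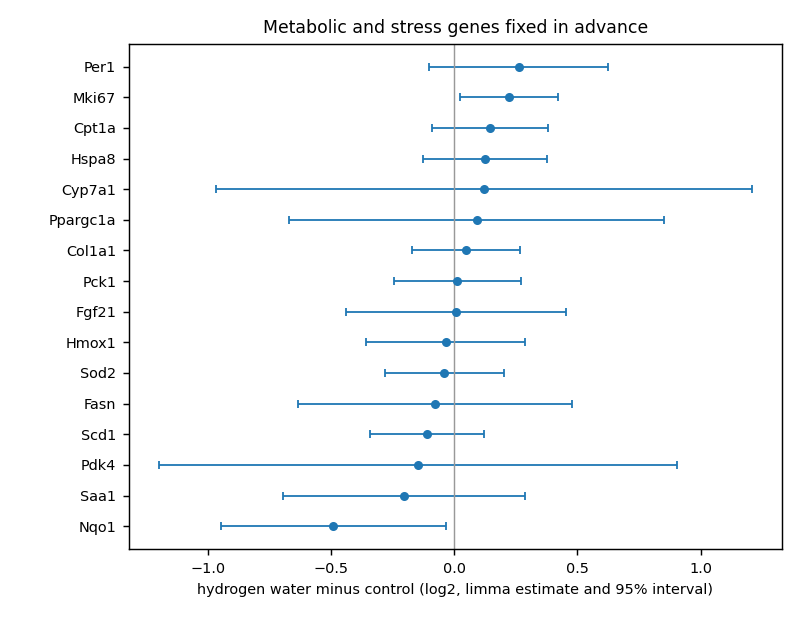
Difference between hydrogen water and control (horizontal axis, log2) for the 16 genes fixed in advance that were measured; points are limma estimates over 4 arrays per group and bars 95% intervals. The intervals of Nqo1 (−0.95 to −0.03) and Mki67 (0.02 to 0.42) leave out 0, and neither passed the adjusted threshold.

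Of 46 gene and marker lists fixed before the data were examined, 10 passed limma's camera test with its preset correlation of 0.01 between genes, 6 higher and 4 lower with hydrogen water. With the correlation estimated for each list, 0 passed (lowest adjusted p = 0.824). The estimates for these 10 lists lay between 0.17 (CAR, PXR and AhR targets) and 0.61 (sinusoidal endothelial cell markers). They lie above the preset 0.01, so the preset-correlation p-values given below overstate the evidence for these lists. By fry 0 passed (lowest adjusted p = 0.855). By an exact permutation test of the list means 0 passed (lowest adjusted p = 0.761). The smallest two-sided p that the permutation test allows is 0.0286. After adjustment over 46 lists, a list could pass only if many others also reached that p, so this count decides little. Quantile normalization gave 13 lists, 11 higher and 2 lower, of which 7 were among the 10; the calls of endoplasmic reticulum stress, NRF2 targets and CAR, PXR and AhR targets were lost, with means of −0.12, −0.16 and −0.14 there against −0.13, −0.16 and −0.14. In all 10, 0 members passed the threshold over all genes.

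Markers of Kupffer cells, the resident macrophages of the liver, were higher with hydrogen water in 14 of 14 measured members, by a mean of 0.34 (camera adjusted p = 1.55e-06). The call was lost with an estimated correlation (p = 0.0575, adjusted p = 0.824). The per-array mean was 0.17 ± 0.26 (SD, n = 4) with hydrogen water and −0.17 ± 0.21 (SD, n = 4) in controls. The scavenger receptor Cd163 differed by 0.63 (SE 0.22), the complement subunit C1qc by 0.62 (SE 0.19), Csf1r, the receptor for macrophage colony-stimulating factor, by 0.59 (SE 0.21) and the lectin Clec4f by 0.43 (SE 0.13). The list mean was highest on hydrogen water 4 (0.51), and control 3 was the highest control (0.11). Adjusted over the list alone, 0 of the 14 passed.

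Markers of sinusoidal endothelial cells were higher in 12 of 12 measured members, by a mean of 0.28 (camera adjusted p = 7.98e-05). With an estimated correlation this call was lost (p = 0.129, adjusted p = 0.824). The scavenger receptors Stab1 and Stab2 differed by 0.60 (SE 0.15) and 0.56 (SE 0.17), the adhesion molecule Pecam1 by 0.32 (SE 0.10) and Oit3 by 0.36 (SE 0.19). Adjusted over the list alone, 3 passed (Stab1, Stab2 and Pecam1), against 0 over all genes. The mean difference of the list was 0.18 without hydrogen water 2 and 0.19 without control 2. Interferon response genes were higher in 19 of 24 measured members, by a mean of 0.22 (camera adjusted p = 0.000869), and this was lost with an estimated correlation (p = 0.208, adjusted p = 0.824). Stat2, Tap1, Oasl2 and Oas2 differed by 0.56 (SE 0.20), 0.39 (SE 0.12), 0.39 (SE 0.16) and 0.29 (SE 0.11). The per-array mean of this list was 0.11 ± 0.35 (SD, n = 4) with hydrogen water and −0.11 ± 0.07 (SD, n = 4) in controls (exact permutation p = 0.371). It was 0.32 and 0.49 on hydrogen water 3 and 4, but −0.23 and −0.12 on hydrogen water 1 and 2. The Kupffer cell list was also highest on hydrogen water 3 and 4 (0.19 and 0.51). Without hydrogen water 4 the mean difference of the interferon list was 0.10 and the call was lost (camera adjusted p = 0.16). Without hydrogen water 1 that difference was 0.34.

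Genes that male mouse livers express above female livers were lower in 18 of 20 measured members, by a mean of −0.24 (camera adjusted p = 0.000869), which was lost with an estimated correlation (p = 0.108, adjusted p = 0.824). The steroid enzyme Hsd3b5 differed by −1.10 (SE 0.33), Ugt2b38 by −0.53 (SE 0.17), Ugt2b1 by −0.30 (SE 0.14) and the complement gene C8b by −0.23 (SE 0.11). The sex of the animals is not stated in the labels. Without control 2 the mean difference of the male-biased list was −0.16. The per-array mean of that list was −0.25 and −0.24 on hydrogen water 3 and 4, but 0.02 and −0.01 on hydrogen water 1 and 2. Controls 1 to 4 stood at 0.03, 0.35, 0.12 and −0.03 (exact permutation p between groups = 0.114). Female-biased genes had a mean difference of −0.02 over 18 measured members (exact permutation p = 0.914).

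Targets of NRF2, the transcription factor of the oxidant response, were lower in 20 of 27 measured members, by a mean of −0.16 (camera adjusted p = 0.0026), which was lost with an estimated correlation (p = 0.202, adjusted p = 0.824). The carboxylesterase Ces1g differed by −0.52 (SE 0.12), Osgin1 by −0.58 (SE 0.25), Nqo1 by −0.49 (SE 0.21) and Cbr3 by −0.41 (SE 0.19). Adjusted over the list alone, 1 passed (Ces1g). Without control 1 the mean was −0.08 (camera adjusted p = 0.24), and without hydrogen water 2 it was −0.14 (camera adjusted p = 0.0505). Targets of the xenobiotic receptors CAR, PXR and AhR were lower in 18 of 24 measured members, by a mean of −0.14 (camera adjusted p = 0.0164), which was lost with an estimated correlation (p = 0.186, adjusted p = 0.824). Cyp2c55 differed by −0.87 (SE 0.22), Cyp1a1 by −0.42 (SE 0.14), Cyp3a16 by −0.37 (SE 0.18) and Tiparp by −0.34 (SE 0.15); all but Tiparp lay below the median level of tested genes, at 4.69, 3.84 and 3.20. Adjusted over the list alone, 1 passed (Cyp2c55). This call was lost without any of 5 arrays (controls 1, 3 and 4, hydrogen water 1 and 2), where the mean lay between −0.12 and −0.10, and it was −0.23 without control 2. It was also lost over members above the median level (−0.09, camera adjusted p = 0.0982), with the filter on dim probe sets (−0.09, camera adjusted p = 0.119) and with array weights (−0.09, camera adjusted p = 0.144).

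Genes of the endoplasmic reticulum stress response were lower in 23 of 25 measured members, by a mean of −0.13 (camera adjusted p = 0.00233), which was lost with an estimated correlation (p = 0.214, adjusted p = 0.824). The chaperone genes Dnajb9, Sdf2l1 and Pdia4 differed by −0.39 (SE 0.14), −0.44 (SE 0.20) and −0.26 (SE 0.11), and Herpud1 by −0.23 (SE 0.13). Without control 2 the mean was −0.08 (camera adjusted p = 0.0583). Heat shock genes were higher in 20 of 24 measured members, by a mean of 0.12 (camera adjusted p = 0.00473), which was lost with an estimated correlation (p = 0.233, adjusted p = 0.824). Hspb1 differed by 0.70 (SE 0.19), Hspa4l by 0.32 (SE 0.13), Hsp90aa1 by 0.27 (SE 0.13) and Ahsa1 by 0.22 (SE 0.11). The mean was 0.04 without control 4 (camera adjusted p = 0.419) and 0.09 without hydrogen water 4 (camera adjusted p = 0.0907), and 0.07 with array weights (camera adjusted p = 0.144).

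Gluconeogenesis and fasting response genes were higher in 20 of 24 measured members, by a mean of 0.17 (camera adjusted p = 0.00473), which was lost with an estimated correlation (p = 0.211, adjusted p = 0.824). The kinase Sik1 differed by 0.66 (SE 0.30), Trib1 by 0.34 (SE 0.13), and the transaminases Got1 and Gpt2 by 0.31 (SE 0.14) and 0.26 (SE 0.12), beside the 0.01 of Pck1. The mean was 0.11 without hydrogen water 4 (camera adjusted p = 0.163) and 0.15 without control 3 (camera adjusted p = 0.0658), and 0.13 with array weights (camera adjusted p = 0.0642). Fatty acid oxidation genes were higher in 22 of 29 measured members, by a mean of 0.10 (camera adjusted p = 0.022), which was lost with an estimated correlation (p = 0.268, adjusted p = 0.824). The carnitine transporter Slc22a5 differed by 0.31 (SE 0.13), Acot2 by 0.31 (SE 0.15), Crat by 0.26 (SE 0.12) and Cpt2 by 0.21 (SE 0.10). Control 3 had the lowest mean of this list (−0.28); without it the mean difference was 0.02 (camera adjusted p = 0.724). The call was also lost without control 4 (0.10), hydrogen water 1 (0.10) or hydrogen water 4 (0.09), with array weights (0.05, camera adjusted p = 0.319) and with the filter on dim probe sets, where the mean was still 0.10 (camera adjusted p = 0.0685). With each array centred on its median, the mean was 0.06 (camera adjusted p = 0.0242), and with quantile normalization it was 0.13 (camera adjusted p = 2.57e-05).

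**Figure D3:**
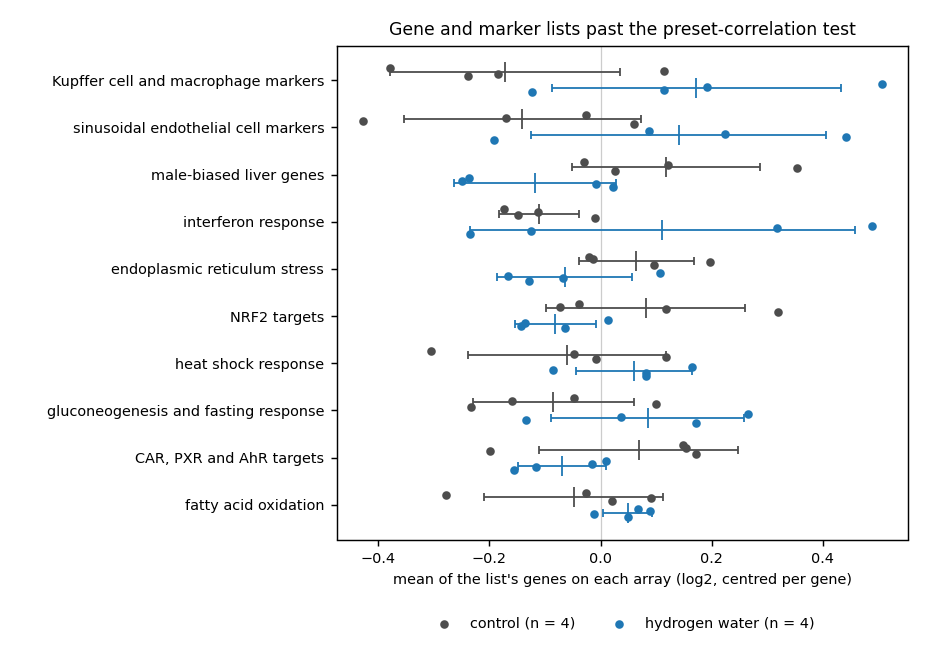
Mean of each of the 10 lists on each array (horizontal axis, log2 signal centred per gene); points are arrays, vertical ticks group means and bars the SD over 4 arrays. Groups overlapped in all 10, and the Kupffer cell list was 0.51 on hydrogen water 4 and 0.11 on control 3.

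The other 36 lists did not pass camera's preset-correlation test. Among metabolic lists, the mean difference was 0.09 for amino acid breakdown and the urea cycle, 0.08 for PPARalpha targets other than oxidation enzymes, −0.13 for glycogen metabolism, 0.06 for lipoprotein and lipid droplet genes, −0.05 for ketone body metabolism and −0.07 for bile acid synthesis and transport. It was 0.03 for fatty acid and triglyceride synthesis, 0.01 for cholesterol synthesis, −0.00 for glycolysis and glucose use, −0.05 for the mitochondrial respiratory chain and 0.08 for mitochondrial biogenesis and dynamics. Adjusted over the list alone, 1 glycogen gene passed (Ppp1r3c, adjusted p over that list = 0.00145) and 1 bile acid gene, Cyp8b1, which makes cholic acid (a difference of 0.53, SE 0.13, adjusted p over that list = 0.0453). Neither passed over all genes with limma (adjusted p = 0.558 and 0.617).

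Among stress, signalling and growth lists, the mean difference was −0.03 for antioxidant enzymes other than NRF2 targets, 0.07 for the ATF4 and amino acid response, −0.07 for the acute phase response, 0.02 for the NF-kB and cytokine response, 0.08 for glucocorticoid targets and 0.09 for immediate early genes. It was 0.05 for the circadian clock, 0.02 for collagen and extracellular matrix, −0.04 for the cell cycle, −0.01 for p53 targets, 0.00 for autophagy and lysosome and −0.02 for cytosolic ribosomal proteins. Among markers of cell types, the mean difference was 0.01 for hepatocytes, −0.02 for pericentral and 0.10 for periportal hepatocytes, −0.19 for stellate cells and fibroblasts, −0.20 for cholangiocytes, −0.03 for neutrophils, 0.01 for B and plasma cells and 0.00 for T and NK cells. For tissues that could be carried along it was −0.09 for erythroid cells, −0.18 for pancreatic acinar cells, −0.14 for adipocytes and 0.02 for skeletal muscle. The adipocyte list reached an exact permutation p of 0.0286, the smallest the design allows, and an adjusted p of 0.761 by the same exact test. In 9 lists the mean, the median or camera's direction differed in sign: erythroid, neutrophil, B cell and T cell markers, fatty acid synthesis, NF-kB, glycolysis, cholesterol synthesis, and autophagy. Ribosomal protein genes stood at −0.35 on control 3, −0.21 on hydrogen water 4 and 0.22 on control 2.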

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

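The counts of other splits for genes and lists were chosen before the data were examined; the tests on Kupffer cell markers and their counts of splits were chosen after the result was seen, and so was the rule that a value had to exceed its spread to count against an explanation.

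Single arrays lay far from the other 3 of their group in 5 named genes and 2 lists, out of 244 groups of 4 tested, where chance alone gives about 5%. Wsb1 was 8.17 on hydrogen water 2 against 8.61 to 8.70 on the other hydrogen water arrays. Car8 was 9.10 on hydrogen water 4 against 9.51 to 9.55. Pecam1 was 7.09 on hydrogen water 2 against 6.80 to 6.84. Hspa4l was 8.13 on hydrogen water 3 against 8.54 to 8.62. Cpt1a was 12.66 on control 1 against 12.77 to 12.79. The mean of the CAR, PXR and AhR target list was −0.20 on control 2 against 0.15 to 0.17, and that of the adipocyte marker list was −0.19 on hydrogen water 4 against −0.04 to −0.02.

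Chance could not be excluded for the number of genes at an unadjusted p under 0.01 or of lists that passed. For genes past the adjusted threshold the real count was 0, so all 35 splits of the 8 arrays into 4 and 4 had to give at least as many and the comparison decides nothing. At an unadjusted p under 0.01, 6 of the 35 splits, the real one included, gave at least the real 308 genes. The highest other split, controls 1, 2 and 4 with hydrogen water 2 against the rest, gave 572. For lists past camera's preset-correlation test, 20 of the 35 splits, the real one included, gave at least the real 10. The other splits gave a median of 10.5 lists and at most 17.

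Kupffer cell and macrophage markers were higher on hydrogen water arrays in 14 of 14 members, 10 of them above the median level of tested genes and 0 of them in another list. Log2 signals with hydrogen water against control were 8.82 and 8.72 for Lyz2, 8.41 and 7.98 for Clec4f and 8.12 and 7.82 for C1qb. Of the 35 splits, the real one included, 2 gave a difference of the list mean at least as large as the real 0.34. The highest other was 0.46, so chance was not excluded. A lower share of hepatocytes would raise all other cell types alike. Hepatocyte markers themselves differed by 0.01. Endothelial markers differed by 0.28, and stellate, cholangiocyte, neutrophil, B cell and T cell markers by −0.19, −0.20, −0.03, 0.01 and 0.00. The Kupffer list minus the stellate list differed by 0.54 and minus the cholangiocyte list by 0.54 (exact permutation p = 0.0857 each), minus the neutrophil, B cell and T cell lists by 0.37, 0.33 and 0.34 (exact permutation p = 0.0571 each), minus the mean of all 6 lists by 0.37 (exact permutation p = 0.0857) and minus the endothelial list by 0.06 (exact permutation p = 0.8), so that explanation stays open. Without hydrogen water 4, 67.7% of the difference was left, or 0.23 (SE 0.14). That lay above the level at which 1 array would be held to carry the difference, but by less than this SE. It was therefore not excluded that this array carries much of the difference. A change in macrophage number or activity with hydrogen water also stays open and was not tested.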

How the results depend on the processing

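Leaving out control 3 and hydrogen water 4 together, and leaving out small non-coding RNAs, were alternatives chosen after seeing the data; the others were planned. Genes past limma's adjusted p of 0.05 numbered 0 to 1 when single arrays were left out (Sucnr1 without control 2, Aqp8 without control 3) and 3 without both control 3 and hydrogen water 4 (Aqp8, Mir297b and Usp17ld); these 4 were named after their values were seen. None of the 75 genes named by rule passed in any alternative run (lowest adjusted p 0.0563). Genes at an unadjusted p under 0.01 numbered 168 after the filter on dim probe sets, which tested fewer genes (9901), 542 with array weights, and 170 (without hydrogen water 3) to 509 (without hydrogen water 2) with single arrays left out, 204 without control 1. Lists past camera numbered 6 with array weights (CAR, PXR and AhR targets, heat shock, gluconeogenesis and fatty acid oxidation were lost), 5 without both arrays (fatty acid oxidation, gluconeogenesis, heat shock, interferon and CAR, PXR and AhR targets were lost), 0 with an estimated correlation, 0 by fry, 0 by exact permutation, and 7 to 12 with single arrays left out. List means at an unadjusted exact permutation p under 0.05 numbered 1; this was 0 with medians over members and 1 to 3 with single arrays left out. The mean difference of the ATF4 list turned to −0.0034 without both arrays. In some alternative the sign changed for 22 of 46 lists and 8 of 75 named genes, none of them called there. Over the list results, 62 lost and 24 gained a call. The losses include all 10 lists with an estimated correlation, by fry and by exact permutation, tests that do not preset the correlation between genes. The exact permutation test could hardly have kept a call after adjustment over 46 lists, so its losses add little. The cause of the other changes was not tested. A pseudocount (the values are log2) and lists over probe sets with several symbols were not run.

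Replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated at −0.05, 0.09, −0.05 and −0.19, and 0 arrays correlated best with their own number. With the replicate block, 0 genes passed, 285 had an unadjusted p under 0.01 and 13 lists passed camera; sign flips within numbers gave 0 list means, since their smallest p exceeds 0.05.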

Other observations

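All tests in this part were chosen after the result was seen.

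Transcripts known to be retained in the nucleus or to keep introns were mostly higher on the hydrogen water arrays. Malat1, a long non-coding RNA of nuclear speckles, stood at 10.08 ± 0.75 (SD, n = 4) against 8.63 ± 0.91 (SD, n = 4) in controls. The splicing kinase Clk1 differed by 0.45 (SE 0.12), the cyclin Ccnl1 by 0.54 (SE 0.19) and Nktr by 0.43 (SE 0.17). Of 29 measured members of a list of such transcripts, written after Pnisr, Rsrp1, Leng8 and Wsb1 had been seen and leaving those out, 26 were higher and 8 had an unadjusted limma p under 0.05, all 8 higher.

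A wider class of nuclear transcripts being higher with hydrogen water is a hypothesis that the data leave open. The mean of that list differed by 0.25 with an exact permutation p of 0.114, and by camera with an estimated correlation p was 0.110. The list stood at 0.40 on hydrogen water 4 and −0.20 on hydrogen water 2, and its difference was 0.15 without hydrogen water 4. A shift in RNA recovery might move small nucleolar RNAs too; their median differed by −0.14 (exact permutation p = 0.83) and by 0.13 without hydrogen water 4, so the sign rests on that array and the explanation stays open.

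Bcl6, a transcriptional repressor, ranged over 3.60 on the log2 scale between arrays, and the growth hormone targets Socs2 and Cish over 3.72 and 2.26, or 1.16 and 1.69 without control 3. Swings in growth hormone signalling between animals might set Bcl6 against both. Over the 8 arrays Bcl6 and their mean correlated at r = −0.277 (permutation p = 0.514) and Spearman's rho −0.405 (permutation p = 0.327), with 1 relation computed, and at r = −0.698 without the 2 arrays farthest from the median in Bcl6, controls 1 and 2; that value rests on control 3, without which r over the remaining 5 arrays was −0.219. After taking out the group means r was −0.125. The mean of Cish and Socs2 minus Bcl6 differed between groups by 1.79 with an exact permutation p of 0.2, so neither a link nor a difference between the drinking groups was shown.

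Among 12146 probe sets unnamed here, 370 (3.05%) had an unadjusted limma p under 0.01, 332 higher and 38 lower with hydrogen water, and 0 passed the adjusted threshold. They were dim, with a median level of 4.37 (4.84 for the 370) against 5.87 for tested genes. The split was 281 higher and 66 lower with quantile normalization, and 271 and 73 with each array centred on its median. Of the 35 splits of the arrays, the real one included, 2 gave at least as many at an unadjusted p under 0.01.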
